A study of Mus musculus with 6 samples.

How the data were processed

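Gene expression was measured by RNA sequencing in 6 libraries of cultured adherent bone marrow cells labelled as macrophages, 3 from young and 3 from old mice. Per the labels' protocols, RNA of 10000 cells per library was reverse transcribed and amplified with a low-input kit that does not mark the strand, fragmented, and sequenced as read pairs of 100 bp. The deposited values are whole-number counts of reads per gene, and the table holds 39017 Ensembl gene identifiers. Per the submitters' processing notes, the tools included cutadapt 1.18, Trim Galore 0.50, STAR 2.6.1a, HISAT2 2.1.0, Picard 2.18.15, SAMtools 1.9 and StringTie 1.3.4d, with the mm10 build. Which tool made the counts, the annotation release, the treatment of reads that map to several places and the strand setting are not given in the sources used here. Genes that overlap another gene or resemble a copy may therefore share or lose reads, and the share of a gene's exon length that overlaps another gene is given for each named gene where it exceeds 10%. Amplified reads without molecular identifiers are not independent molecules, so intervals on counts cover counting error only.

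Libraries were assigned to age and replicate from the labels. Total counts were 34391206, 34597583 and 35813492 in young replicates 1, 2 and 3 and 43367734, 38030342 and 36136137 in old replicates 1, 2 and 3. Symbols were matched to 37607 of the identifiers, and the unmatched ones held 0.339% to 0.398% of counts per library. Positions and exon overlaps were taken from GENCODE mouse release M21, on the mm10 (GRCm38) build. No column of the table was left unused.

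Counts were analysed in R 4.3.3 with edgeR 4.0.16: filtering by filterByExpr on the age groups, TMM normalization, and the robust quasi-likelihood test, with Benjamini-Hochberg adjustment over the 15567 genes tested and a threshold of 0.05. The log2 fold change is old minus young, and its SE is the absolute log2 fold change divided by the square root of the F statistic. CPM uses the TMM-scaled library sizes, also for genes that were not tested. No replicate block was used. A gene that failed the filter was described by its counts, with an exact permutation test of CPM for Cxcl13 in scipy 1.17.1.

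The 34 gene lists, with 601 distinct genes, and the rule for genes to name were fixed before the data were examined, and 2 of their genes, Flt3l and Ahsp, had no matching identifier. They were tested with camera (limma 3.58.1) at a preset inter-gene correlation of 0.01, with adjustment over the 33 lists that had at least 3 tested members. The lists cover macrophage identity, chemokines, chemokine receptors, inflammatory cytokines and NF-kB targets, interferon-stimulated genes, MHC class I and class II presentation, alternative activation, complement, phagocytosis, lysosome, iron handling, lipid uptake and LXR targets, cholesterol biosynthesis, glycolysis and hypoxia, oxidative phosphorylation, cell cycle, senescence, NRF2 targets, the unfolded protein response, immediate early genes, niche factors, and markers of osteoclasts, neutrophils, dendritic cells, B cells, T and NK cells, stromal cells, osteoblasts, endothelium, erythroid cells, mast cells and basophils, megakaryocytes, and sex. Further lists, of leukocyte-restricted, further B-lineage and juvenile growth genes, were added after the data were examined.

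The genes to name were Cxcl13, Cxcr5, Adgre1 and Siglec1; the 10 higher and 10 lower genes with the largest change among those past the threshold with a mean of at least 5 CPM in the higher group, CPM ranges that do not overlap and a symbol that is not a predicted model; and up to 4 members per list with the smallest p, or the 2 most abundant where none passed. Some genes that the rule names are not reported here. Genes named otherwise are members of the lists or are said to be chosen after their values were seen.

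Alternatives were DESeq2 1.42.0 size factors, upper-quartile factors, scaling without the 50 most abundant genes, the DESeq2 test, limma-voom, a non-robust dispersion, no low-count filter, a filter of at least 50 counts in 3 libraries, a replicate block, a tested fold of at least 2, and leaving out each library. For the lists they were an estimated correlation, fry, DESeq2 size factors, the stricter filter, the block and leaving out each library. With an estimated correlation camera tests on the 4 residual degrees of freedom of the fit, and with the preset on many more. A list can therefore lose its call there whatever its correlation. Restricting the test to genes without an overlapping exon, and leaving out genes whose counts jump between libraries of one age, were added after the data were examined. A jump was a gap of at least 2 in log2(CPM + 1) between neighbouring libraries of one age, at a mean of at least 5 CPM.

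The procedure was tested on simulated data with the means, dispersions and library sizes of the 15567 genes, of which 200 were changed. It recovered 11.9% of genes changed 1.5-fold, 58.2% of those changed 2-fold and 83.3% of those changed 4-fold. Of its 115 calls, 7% were unchanged genes. The real comparison called 10.5% of the genes, a larger share than was changed here, so these rates may differ there. Camera called 0 of 33 unchanged lists and the 1 list of 20 genes that had been moved by 0.6 on the log2 scale. The simulated genes were drawn independently, so list members shared no correlation. Estimates for the real lists reached 0.874 (megakaryocyte markers). The simulation therefore does not show how often camera calls unchanged lists of correlated genes. Python 3.11.15 with pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9 was used for tables and plots.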

Results

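RNA sequencing was performed on adherent cells grown from mouse bone marrow and labelled as macrophages. There were 3 libraries from young animals (3 weeks of age) and 3 from old animals (more than 78 weeks). The mice were wild-type BALB/c, an inbred strain. Marrow was released by crushing the long bones of the limbs, and the cells that stayed attached to the dish were expanded in culture and described by the submitters as positive for F4/80 and CD169, which are surface markers of resident macrophages. Each library was made from 10000 cells. The comparison asks how the age of the animal goes with gene expression in these adherent cells, and the series title places it in work on B-cell acute lymphoblastic leukemia and the chemokine receptor pair CXCR5 and CXCL13. Total counts ranged from 34391206 to 43367734 per library, and 15567 genes entered the test. Values below are CPM, counts scaled to library size, given as mean ± SD over n = 3 libraries per age, and adjusted p-values are from edgeR unless camera, a gene list test, is named. Nothing in the labels says whether the libraries of one age came from separate animals, so the p-values measure the spread between these libraries.

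Old and young libraries separated along the first principal component, which held 57.4% of the variance. The second component held 17.7% and set young replicate 3 apart from the other 5 libraries. In that library the 2 type I collagen genes Col1a1 and Col1a2, the main products of connective tissue cells, took 5.44% of all counts, against 3.00% and 2.66% in the other young libraries and 1.80% to 2.25% in the old ones. Col1a1 was the most abundant gene in all 6 libraries. The changes given below are therefore those of the cultures as a whole and cannot be assigned to macrophages alone. Xist, transcribed from the inactive X chromosome of female cells, had 0 counts in each library, and the Y-linked gene Ddx3y lay between 71.6 and 107.6 CPM in each. Of the 4 tested members of the list of Y-linked genes and Xist, 0 passed the threshold with edgeR, over all genes or adjusted over the list alone, 0 with DESeq2 or limma-voom, and 1 had an unadjusted p under 0.05 (camera adjusted p = 0.835). Without young replicate 3, Ddx3y was called lower (adjusted p = 0.0285). Replicates of one age differed by more than sampling noise in each of the 6 within-age pairs.

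**Figure D1:**
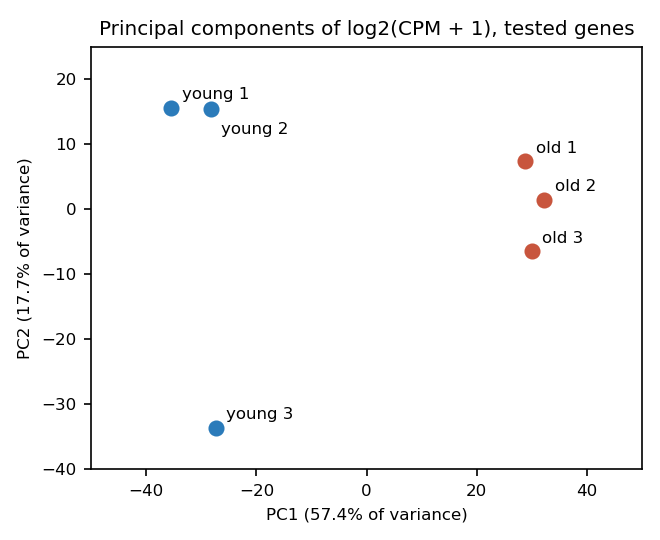
Principal components of log2(CPM + 1) over the 15567 tested genes, with the first component on the x axis (57.4% of variance) and the second on the y axis (17.7%); each point is 1 library. Blue points are young and red points old, and young replicate 3 lies apart from the other 5 libraries on the second component.

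Gene expression differed widely between old and young libraries. At an adjusted p of 0.05, 909 genes were higher and 731 lower in the old libraries, 10.5% of the genes tested. The CPM ranges of the ages did not overlap for 30.2% of tested genes, where chance gives 10%. The genes that fell furthest included several made by bone-forming cells. Ibsp, encoding bone sialoprotein, went from 1204 ± 499.7 to 54.8 ± 20.0 CPM, a log2 fold change of -4.46 with SE 0.42 (adjusted p = 0.00135). Dmp1, a gene of the osteocyte matrix, went from 48.3 ± 17.2 to 0.445 ± 0.106 CPM. The secreted factor C1qtnf3 had a log2 fold change of -7.44 (-8.40 without old replicate 1), and Bmp3, a bone morphogenetic protein, was 87.8-fold lower. Ephb1, Kcnk1, Nell2, Wnt7b, Ifitm5 and Capn6 complete the 10 genes with the largest decreases among those with a mean of at least 5 CPM in young libraries, with log2 fold changes from -7.23 to -4.87. Leaving out 1 library moved the fold of all of these but Capn6 by more than 1.5 times, furthest for Kcnk1 (log2 fold change -11.39 without old replicate 3) and Ephb1 (-10.69 without old replicate 2). Ifitm5, which shares 29.7% of its exon length with another gene model, lost its call without old replicate 2 (adjusted p = 0.0524).

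By the same rule, the 10 genes with the largest increases were all immunoglobulin genes. Igha, the constant region of IgA, went from 0.179 ± 0.310 to 40.9 ± 26.2 CPM (adjusted p = 0.00382), and its 19 young counts were all in young replicate 2. Without that library its log2 fold change went from 7.78 to 13.58 (7.17 without old replicate 3). The remaining young libraries had 0 counts, so the 13.58 depends on the prior count and is not a measured fold. With limma-voom the Igha call was lost (adjusted p = 0.0509). Of the other 9, Ighg1, Ighg2b, Igkv3-10, Igkv1-110, Igkv15-103, Igkv10-96 and Igkv6-23 had 0 counts in every young library. Against a floor of 3 counts over the young group, the old mean was at least 504-fold higher for Igkv1-110 and 213-fold higher for Ighg1. Both are bounds for counting error only and leave out the spread of the old libraries, where Ighg1 had 80, 250 and 364 counts. Igkv4-53 and Igkv1-135 had 4 and 7 counts, all in young replicate 2. Igkv3-10 lost its call without young replicate 3 (adjusted p = 0.0975). Of 35 immunoglobulin gene models tested, 27 were higher (20 to 25 on leaving out 1 library) and 0 lower in old libraries. Variable-region genes resemble one another, so counts of single members are uncertain. Outside the immunoglobulin genes, and chosen after their values were seen, the largest increases included Prg4, encoding lubricin, which was 60.5-fold higher, the adhesion molecule Selp, which platelets carry, 60.8-fold higher, and the protease gene Htra4, 23.5-fold higher, which shares 32.9% of its exon length with Gm16933. The log2 fold change of Selp was 5.93, and 5.26 without old replicate 2 and 7.79 without young replicate 2. The megakaryocyte genes Ppbp and Gp1ba and the mast cell gene Fcer1a were among the same increases. The log2 fold change of Ppbp was 5.62, and 4.94 and 6.49 without those libraries, and that of Gp1ba was 4.07, and 3.31 and 5.03. Selp had 241, 482 and 129 counts in old replicates 1, 2 and 3, where Ppbp had 1266, 2777 and 812 and Gp1ba 183, 376 and 76. Leaving out 1 library moved a count by more than 1.5 times in 5 of 6 cases. Without young replicate 3 there were 1459 higher and 1168 lower genes, without young replicate 1 there were 539 and 432, and without old replicate 1, 2 or 3 the numbers were 418 and 309, 433 and 294, and 492 and 424. After the count of each gene list, a range gives its lowest and highest count over the 6 fits that leave out 1 library.

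**Figure D2:**
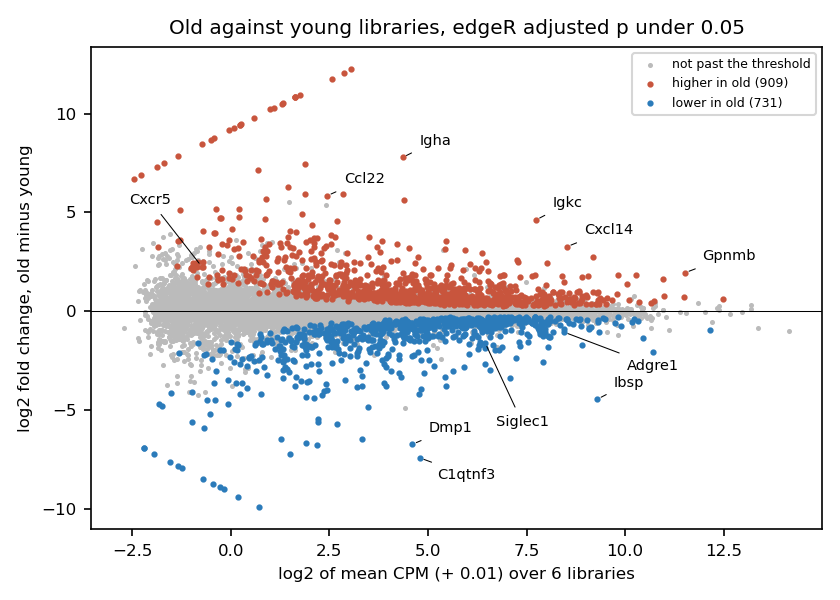
Log2 fold change, old minus young, of each tested gene (y axis) against the log2 of its mean CPM plus 0.01 over the 6 libraries (x axis). Red points are the 909 genes higher and blue points the 731 genes lower in old libraries; the straight bands of points at either edge are genes with 0 counts in one age, whose fitted fold change depends on the prior count.

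Macrophage identity genes were mostly lower in the old libraries. Of 21 tested members, 13 fell (range 8 to 13), 3 rose (range 1 to 3) and 5 did not pass. Siglec1, which encodes CD169, went from 131 ± 6.61 to 43.3 ± 5.28 CPM, a log2 fold change of -1.60 with SE 0.11 (adjusted p = 0.000492). Adgre1, which encodes F4/80, went from 473 ± 77.5 to 226 ± 25.3 CPM, a log2 fold change of -1.06 with SE 0.14 (adjusted p = 0.00499). Csf1r, the receptor for the main macrophage growth factor, was 1.88-fold lower (15.1% of its exon length is shared with Hmgxb3), and the Fc receptor chain Fcer1g 1.83-fold lower. Members that rose included the adhesion molecule Vcam1 (log2 fold change 0.70) and the galectin gene Lgals3 (0.78), the latter lost without old replicate 1 (adjusted p = 0.0533). Siglec1 lies on chromosome 2 at 131069220 to 131086765 and Adgre1 on chromosome 17 at 57358691 to 57483527 of the mm10 build. Both genes were protein-coding, identified as ENSMUSG00000027322 and ENSMUSG00000004730. The list was lower as a set (camera adjusted p = 3.02e-07), a call that was lost with an estimated correlation (adjusted p = 0.326). Adjusted over the list alone, 14 members fell and 3 rose. Beside these genes, leukocyte-restricted genes, a list added after the data were examined, had a median log2 fold change of -0.45, with 16 lower (range 6 to 23) and 0 higher of 36.

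**Figure D3:**
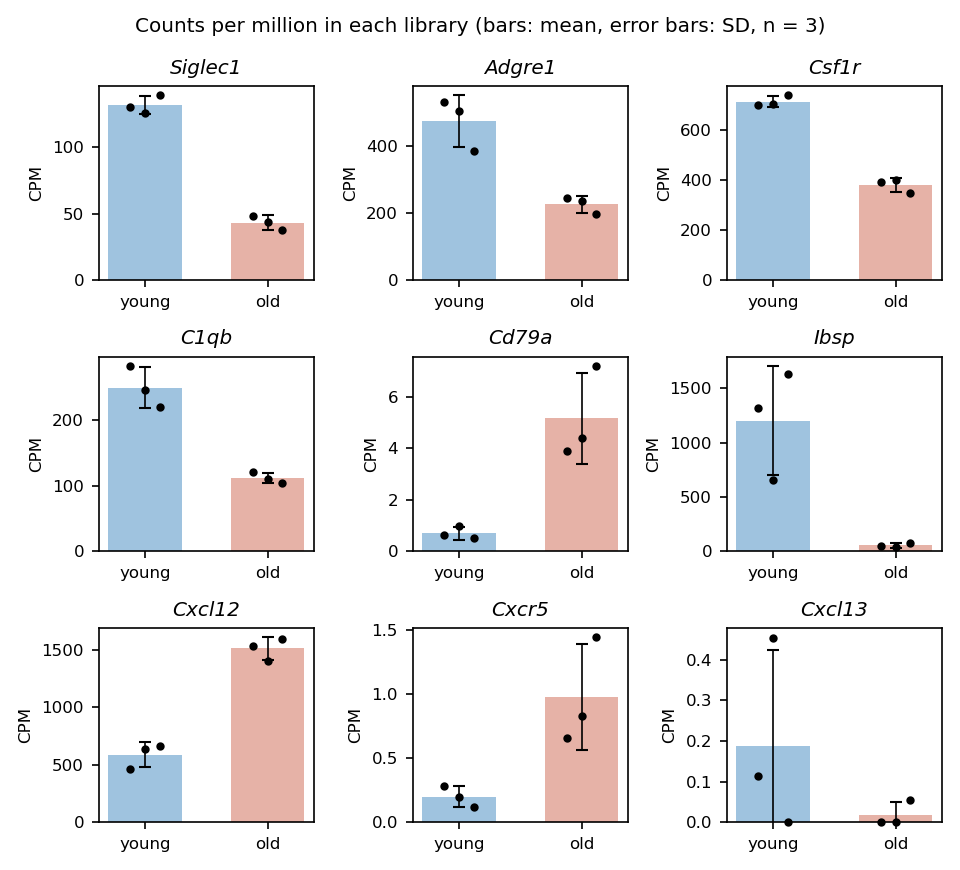
CPM of 9 genes in each library; bars are means of 3 libraries (young blue, old red), error bars are SD and black points are single libraries. Siglec1, Adgre1, Csf1r, C1qb and Ibsp lie lower and Cd79a and Cxcl12 higher in every old library than in every young one; Cxcr5 and Cxcl13 stay under 1.5 CPM.

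The ligand and receptor of the series title were both near the limit of detection. Cxcl13, a chemokine that draws B cells, lies on chromosome 5 at 95956951 to 95961068 (ENSMUSG00000023078). It had 4, 16 and 0 counts in young replicates 1, 2 and 3, and 0, 0 and 2 in old replicates 1, 2 and 3, too few for the edgeR test. Its mean was 0.189 ± 0.235 CPM in young and 0.0185 ± 0.0321 CPM in old libraries. An exact two-sided permutation test of CPM gave p = 0.4, where 0.1 is the smallest that 3 against 3 libraries allow. Young replicate 2 held 16 of the 20 young counts. The pooled counts of 20 and 2 give a young to old ratio of 11.4 with a 95% exact (Clopper-Pearson) interval from 2.76 to 100.4, which covers counting error only. Cxcr5, the receptor of CXCL13 on B cells, lies on chromosome 9 at 44511787 to 44561877 (ENSMUSG00000047880). It had 10, 7 and 4 counts in young and 29, 32 and 52 in old libraries, which is 0.201 ± 0.0833 and 0.979 ± 0.412 CPM. Its log2 fold change was 2.26 with SE 0.51 (adjusted p = 0.0341), and the call was lost on leaving out any single library, with adjusted p between 0.0607 and 0.129. B cell markers rose in the same libraries (below by list), and the mean CPM of Cxcr5 was under 1 in both ages.

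Among chemokines, Cxcl14 rose 9.61-fold, to 668 ± 106 CPM (adjusted p = 0.000341). Pf4, the platelet chemokine that macrophages also make, rose 3.57-fold, and Ccl22, which attracts regulatory T cells, went from 0.182 ± 0.221 to 10.7 ± 7.35 CPM, a log2 fold change of 5.84 that became 7.44 without young replicate 1, 5.26 without young replicate 2 and 5.13 without old replicate 3. Ccl5, Cxcl10, Cxcl9, Ccl8 and Cxcl16 fell, with Cxcl9 at a log2 fold change of -4.26. Of these only the Ccl5 call held without every single library. The Cxcl9 and Cxcl10 calls were lost without old replicate 1 or 2, for Cxcl9 also without young replicate 1 (adjusted p up to 0.0750 and 0.0539). The Ccl8 and Cxcl16 calls were lost without young replicate 1 or 2 or old replicate 2 or 3, for Ccl8 also without old replicate 1 (adjusted p up to 0.102 and 0.0681), and Cxcl16 shares 18.3% of its exon length with Zmynd15. In all, 5 of 23 tested chemokines rose (range 3 to 4), 5 fell (range 1 to 8) and 13 did not pass, and the list was not called (camera adjusted p = 0.879). The estimated-correlation p was 0.962, and adjusted over the list alone the counts were 5 and 8. Of 13 chemokine receptors, 4 rose (range 1 to 2) and 2 fell (range 1 to 4). Ackr3, a scavenging receptor for CXCL12, rose 9.27-fold, while Ccr2, the receptor that brings monocytes out of the marrow, fell 5.63-fold, from 55.3 ± 10.7 to 9.80 ± 1.82 CPM (adjusted p = 0.000787). Ccr3 and Ccr7 rose with Cxcr5, and Cxcr3 fell at low levels. The Cxcr3 call held only without young replicate 3 among the fits that leave out 1 library (adjusted p otherwise up to 0.0951), and the Ccr3 call was lost without young replicate 2 and without each old replicate (adjusted p up to 0.108). The Ccr7 call held only without old replicate 1 (adjusted p otherwise up to 0.108), and its log2 fold change went from 2.02 to 1.41 without old replicate 3. The receptor list had a camera adjusted p of 0.638, with 5 higher and 4 lower adjusted over the list alone.

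Interferon-stimulated genes were lower in old libraries. Of 28 tested members, 16 fell (range 4 to 23), 0 rose and 12 did not pass. Ifi27l2a went from 153 ± 18.5 to 45.9 ± 2.68 CPM (log2 fold change -1.74, SE 0.11, adjusted p = 0.000473). The RNA sensor gene Dhx58 fell 1.84-fold and the antiviral gene Mx1 6.29-fold at a low level. The camera adjusted p was 1.5e-15 and the call was lost with an estimated correlation (adjusted p = 0.399). Adjusted over the list alone, 23 members fell.

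Of 14 tested MHC class I members, 0 rose and 4 fell (range 1 to 6), among them the peptide transporter gene Tap1 (142 ± 19.3 to 82.0 ± 4.36 CPM, adjusted p = 0.00645). Tapbp, H2-T23 and B2m were the other 3, with log2 fold changes of -0.58, -0.78 and -0.48, and Tapbp shares 24.9% of its exon length with another gene model. The Tapbp call was lost without old replicate 1 or 2 (adjusted p up to 0.0682), and those of H2-T23 and B2m without young replicate 1 or 2 or old replicate 1 or 2 (adjusted p up to 0.0974 and 0.130). The class I list was lower (camera adjusted p = 0.000537, adjusted p = 0.368 with an estimated correlation), with 5 lower adjusted over the list alone. Of 13 MHC class II members, 0 fell and 4 rose (range 1 to 3), led by H2-Eb1 (3.86 ± 0.414 to 10.8 ± 0.991 CPM, adjusted p = 0.00189). Cd74, the invariant chain, rose 1.74-fold, a call lost without young replicate 1 or 2 or old replicate 2 or 3 (adjusted p up to 0.0868). H2-Ob and H2-Ab1 also passed, and both calls were lost without any single library (adjusted p up to 0.138 and 0.168). The class II list was higher (camera adjusted p = 0.0464), a call lost without young replicate 2 or 3 or old replicate 2 or 3 (adjusted p up to 0.238) and with an estimated correlation (adjusted p = 0.454). Adjusted over the list alone, 6 members rose and 1 fell, and B cells, whose markers rose too, express these genes as well.

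Complement genes were lower in old libraries, with 6 of 14 members down (range 3 to 6) and 0 up. Macrophage identity genes (median log2 fold change -0.63) and leukocyte-restricted genes (-0.45) fell in the same libraries. The 3 chains of C1q, which starts the classical pathway, all fell. C1qb went from 249 ± 31.3 to 112 ± 8.10 CPM (adjusted p = 0.00142), C1qc fell 1.87-fold and C1qa 2.05-fold. Properdin, encoded by Cfp, fell 1.52-fold, a call lost without old replicate 2 (adjusted p = 0.0549). C3 and Cfb were the other 2, with calls lost without young replicate 1 or 2 or old replicate 1 or 2, for C3 also without young replicate 3 (adjusted p up to 0.134 and 0.121), and Cfb shares 79.5% of its exon length with another gene model. The list was called (camera adjusted p = 9.77e-05) and was lost with an estimated correlation (adjusted p = 0.235), with 6 lower adjusted over the list alone.

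Phagocytosis and scavenger receptor genes were mixed, with 3 of 22 higher (range 3 to 5) and 4 lower (range 0 to 6). Itgax, encoding CD11c, rose 5.28-fold, Cd36, a receptor for oxidized lipids, 1.97-fold (294 ± 37.7 to 577 ± 26.8 CPM) and Axl 1.46-fold. Marco had a log2 fold change of -4.35, and -5.35 without old replicate 3, and its call was lost without old replicate 2 (adjusted p = 0.0549). The list was not called (camera adjusted p = 0.855), with 3 higher and 4 lower adjusted over the list alone. Of 15 alternative activation genes, 2 rose (range 1 to 3) and 1 fell (range 1 to 5). Mrc1, the mannose receptor, went from 299.7 ± 18.0 to 153 ± 10.5 CPM, and Pparg rose 1.94-fold. Clec7a rose as well, a call lost without young replicate 1 and without each old replicate (adjusted p up to 0.0866). For this list the camera adjusted p was 0.556, with 4 higher and 5 lower adjusted over the list alone.

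Lysosomal genes included some of the most abundant transcripts. Gpnmb, a glycoprotein of lipid-laden macrophages, rose 3.85-fold to 4666 ± 153 CPM, and the protease gene Ctsl 3.05-fold to 2981 ± 63.1 CPM, although Ctsl shares 26.8% of its exon length with another gene model. Lgmn fell 1.45-fold, and Grn fell 1.67-fold, the latter lost without old replicate 1 or 2 (adjusted p up to 0.0699). In all, 3 of 28 members rose (range 2 to 6), 3 fell (range 1 to 7) and 22 did not pass (camera adjusted p = 0.870), and 4 and 7 did when adjusted over the list alone. Of 15 iron handling genes, 3 rose (range 1 to 3) and 0 fell. Slc48a1, a heme transporter gene, rose 1.42-fold and Hmox1, the heme-degrading oxygenase, 1.39-fold, with the Hmox1 call lost without each old replicate (adjusted p up to 0.0763). Steap3 rose too, a call that held only without young replicate 3 (adjusted p otherwise up to 0.107). The iron list had a camera adjusted p of 0.108, with 4 higher adjusted over the list alone. Among 17 genes of lipid uptake and LXR targets, 4 rose (range 1 to 4) and 5 fell (range 3 to 5). Fabp4 rose from 25.2 ± 1.79 to 63.3 ± 1.14 CPM, whereas Scd2, a fatty acid desaturase, fell 2.56-fold, the cholesterol exporter Abca1 2.53-fold and Pltp 2.40-fold, although Pltp shares 19.3% of its exon length with Ctsa. That list had a camera adjusted p of 0.161, with 4 higher and 6 lower adjusted over the list alone.

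Cholesterol biosynthesis genes were lower, with 7 of 21 members down (range 1 to 10) and 0 up. Lss, which encodes lanosterol synthase, went from 139.8 ± 13.7 to 96.1 ± 1.89 CPM (adjusted p = 0.0113). Hmgcs1, Lss and Mvd fell by 0.50, 0.54 and 0.60 on the log2 scale, with calls lost without old replicate 1 or 2 (adjusted p up to 0.0619, 0.0619 and 0.111), for Lss also without old replicate 3 and for Mvd without young replicate 2. Hmgcs1 shares 12.1% of its exon length with another gene model. The list was lower (camera adjusted p = 4.73e-06, adjusted p = 0.235 with an estimated correlation), and 13 members fell when adjusted over the list alone. Glycolysis and hypoxia genes were lower too, 7 of 22 down (range 3 to 14) and 1 up, and without old replicate 1 or 2 only Slc16a3, Pfkl and Ndrg1 stayed called lower. The lactate exporter Slc16a3 fell 3.97-fold, the phosphofructokinase gene Pfkl 1.57-fold and Ndrg1 1.55-fold, while the angiogenic factor Vegfa rose 1.42-fold. This list had a camera adjusted p of 4.73e-06, lost with an estimated correlation (adjusted p = 0.454), with 10 lower and 1 higher adjusted over the list alone.

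Oxidative phosphorylation genes gave 0 calls among 29 with edgeR, over all genes or adjusted over the list alone, and 0 with DESeq2 or limma-voom, while 2 had an unadjusted p under 0.05 and 2 were called lower without young replicate 3. Atp5b was at 1324 ± 18.0 and 1456 ± 57.2 CPM and Atp5a1 at 994 ± 98.8 and 1051 ± 29.0 CPM in young and old libraries, and the list was not called (camera adjusted p = 0.879). Of 32 cell cycle genes, 3 rose (range 0 to 6) and 0 fell: Cdc20 1.29-fold, Rrm2 1.46-fold and Kif20a 1.36-fold. The calls of Cdc20 and Kif20a held only without young replicate 3 (adjusted p otherwise up to 0.118 and 0.159), and that of Rrm2 was lost without young replicate 1 or old replicate 1 or 2 (adjusted p up to 0.131). Kif20a shares 29.3% of its exon length with Cdc23. The cell cycle list had a camera adjusted p of 0.0743, with 8 higher adjusted over the list alone.

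Of 22 genes of senescence and its secretory factors, 6 rose (range 2 to 5) and 3 fell (range 2 to 3). The elastase gene Mmp12 rose from 153 ± 71.9 to 1018 ± 301 CPM (adjusted p = 0.00459) and Igfbp4 rose 1.84-fold, while Igfbp3 fell 10.1-fold and Cdkn1a, the cell cycle inhibitor p21, fell 1.64-fold. The list was not called (camera adjusted p = 0.368), with 8 higher and 4 lower adjusted over the list alone. NRF2 targets of the oxidative stress response rose, 3 of 20 (range 2 to 4) with 0 down. Nqo1, a quinone reductase, rose 3.58-fold to 39.5 ± 4.79 CPM and Slc7a11, the cystine transporter, rose 2.96-fold, while the call of Txnrd1 held only without young replicate 3 (adjusted p otherwise up to 0.121). The list had a camera adjusted p of 0.00155, lost with an estimated correlation (adjusted p = 0.454), with 6 higher adjusted over the list alone. Immediate early genes rose, 4 of 20 (range 3 to 10) with 0 down: Maff 3.23-fold, Atf3 1.62-fold, Fosl2 1.55-fold and Fosl1 1.81-fold, the last sharing 57.2% of its exon length with Ccdc85b and lost without old replicate 2 (adjusted p = 0.0524). Camera gave an adjusted p of 0.00937, lost with an estimated correlation (adjusted p = 0.703) and without young replicate 1 or 2 (adjusted p up to 0.0798), with 9 higher and 1 lower adjusted over the list alone. Of 20 unfolded protein response genes, 4 rose (range 0 to 5) and 0 fell (range 0 to 1). They were Chac1, Trib3, Atf4 and Ppp1r15a, with log2 fold changes of 0.99, 1.10, 0.53 and 0.88, and Chac1 lost its call without young replicate 2 (adjusted p = 0.0512). The other 3 calls held only without young replicate 3, with adjusted p otherwise up to 0.106, 0.126 and 0.150. This list was not called (camera adjusted p = 0.352), with 4 higher adjusted over the list alone.

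Inflammatory cytokines and NF-kB targets gave 3 higher (range 3 to 4) and 2 lower (range 1 to 4) genes of 22. Il1rn, the interleukin 1 receptor antagonist, rose from 186 ± 31.7 to 519 ± 57.1 CPM, Socs3 rose 1.98-fold and Il6 rose 4.48-fold from 1.11 CPM. Saa3, an acute phase protein, fell 15.5-fold, from 53.3 ± 24.2 to 3.42 ± 1.64 CPM. The list was not called (camera adjusted p = 0.879), with 4 higher and 3 lower adjusted over the list alone. Of 19 niche and B-lineage support factors, 4 rose (range 3 to 6) and 3 fell (range 2 to 3). Kitl, encoding stem cell factor, rose to 135 ± 15.9 CPM (log2 fold change 1.32), Hgf rose 2.00-fold, and Tnfsf13, encoding the B cell factor APRIL, rose from 0.443 ± 0.191 to 4.92 ± 0.438 CPM but shares 60.0% of its exon length with Tnfsfm13. Bmp2 fell 2.61-fold. As a list they had a camera adjusted p of 0.401, with 6 higher and 3 lower adjusted over the list alone.

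Markers of other cell types were measured to describe what else the cultures held. B cell markers rose, 7 of 8 tested (range 4 to 7), and all 8 when adjusted over the list alone. Ms4a1, encoding CD20, went from 0.823 ± 0.205 to 7.73 ± 3.41 CPM and Cd79a from 0.708 ± 0.252 to 5.17 ± 1.77 CPM (adjusted p = 0.00382). Ighm rose 3.57-fold and Igkc 24.5-fold, to 411 ± 49.4 CPM, with 894, 753 and 111 counts in young replicates 1, 2 and 3. The Cd79b call held only without young replicate 3 (adjusted p otherwise up to 0.125), the Ebf1 call was lost without old replicate 1 or 2 (adjusted p up to 0.0518), and the Jchain call without young replicate 1 or 2 or old replicate 1 or 3 (adjusted p up to 0.0578). The list was higher (camera adjusted p = 1.4e-10, adjusted p = 0.235 with an estimated correlation). Mast cell and basophil markers rose, 5 of 10 (range 2 to 5) with 0 down. The protease gene Cpa3 went from 8.56 ± 1.09 to 32.5 ± 9.79 CPM and Fcer1a, the IgE receptor, rose by 4.03 on the log2 scale (3.40 without old replicate 3), while the Mcpt8 call held only without young replicate 3 (adjusted p otherwise up to 0.0799) and the Gata2 call was lost without young replicate 2 and without each old replicate (adjusted p up to 0.0892). Their camera adjusted p was 1.54e-06, lost with an estimated correlation (adjusted p = 0.345), with 8 higher adjusted over the list alone. Megakaryocyte markers rose, 3 of 8 (range 0 to 5), with Ppbp going from 0.834 ± 0.736 to 41.2 ± 27.0 CPM. The Ppbp call was lost without young replicate 3 (adjusted p = 0.0525), and those of Gp1ba and Itga2b without young replicate 1 or 3 or old replicate 1 or 2 (adjusted p up to 0.0649 and 0.140). This list had a camera adjusted p of 0.000108, lost with an estimated correlation (adjusted p = 0.454), with 4 higher adjusted over the list alone.

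Osteoblast markers were lower, 5 of 10 (range 3 to 7) with 0 up. Beside Ibsp and Dmp1, Omd fell 2.94-fold and the transcription factor gene Sp7 2.04-fold, the latter lost without old replicate 1 or 3 (adjusted p up to 0.0706). The list was lower (camera adjusted p = 1.47e-11, adjusted p = 0.235 with an estimated correlation), with 8 lower adjusted over the list alone. Mesenchymal stromal markers were mixed, 5 of 22 higher (range 3 to 7) and 3 lower (range 0 to 3). Cxcl12, a chemokine of the marrow stroma, rose from 589 ± 109 to 1511 ± 97.4 CPM, the BMP antagonist gene Grem1 rose 8.44-fold and Pdgfra 2.35-fold. Acta2 rose 1.64-fold, a call lost without old replicate 1 or 2 (adjusted p up to 0.0611). Postn, Lum and Lepr fell, with the Postn call lost without old replicate 1 or 2 (adjusted p up to 0.0730). The Lum call held only without old replicate 2 or 3 and the Lepr call only without young replicate 2 (adjusted p otherwise up to 0.0894 and 0.135). The summed CPM of the stromal list was 54502 ± 24588 in young and 35356 ± 4145 in old libraries, against 10958 ± 982 and 7956 ± 372 for the macrophage identity list. The stromal list was not called (camera adjusted p = 0.556), with 6 higher and 5 lower adjusted over the list alone.

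Neutrophil and granulocyte precursor markers were lower as a list, with 2 of 15 down (range 0 to 4) and 1 up. Prtn3 and Fcnb, granule protein genes, fell 2.26-fold and 2.82-fold, and the collagenase gene Mmp8 rose 2.66-fold. The Prtn3 call was lost without old replicate 1 or 2 (adjusted p up to 0.0562) and the Fcnb call without young replicate 1 or 2 or old replicate 1 (adjusted p up to 0.0773). Their camera adjusted p was 0.00937, lost with an estimated correlation (adjusted p = 0.703) and without young replicate 2 (adjusted p = 0.138), with 1 higher and 2 lower adjusted over the list alone. T and NK cell markers gave 0 calls among 9 members with edgeR (range 0 to 2, all lower) and 0 with limma-voom, while DESeq2 called 2 lower, 3 had an unadjusted p under 0.05 and 2 were lower adjusted over the list alone. Lck was at 4.95 ± 1.81 and 3.30 ± 2.28 CPM and Nkg7 at 4.81 ± 1.93 and 2.22 ± 1.06 CPM in young and old libraries. That list had a camera adjusted p of 0.0485, lost with an estimated correlation (adjusted p = 0.703) and without young replicate 1 or 2 (adjusted p up to 0.261). Of 11 osteoclast genes, Atp6v0d2 rose 6.10-fold and Acp5, the tartrate-resistant phosphatase, 2.23-fold, with 2 up (range 2 to 3), 0 down (range 0 to 1), 2 higher adjusted over the list alone and a camera adjusted p of 0.127. Of 6 dendritic cell markers, Tcf4 fell 1.36-fold, and of 11 endothelial markers, Cldn5 fell by 2.45 on the log2 scale (3.22 without old replicate 3). The first call held only without young replicate 3 and the second only without old replicate 3 (adjusted p otherwise up to 0.165 and 0.169). Those lists were not called (camera adjusted p = 0.638 and 0.352), with 1 lower for the first and 1 higher and 2 lower for the second adjusted over the list alone. Of the erythroid markers only Epor had enough counts, at 0.757 ± 0.116 CPM in young libraries with a log2 fold change of 0.98 that did not pass (adjusted p = 0.0882), 1 higher adjusted over the list alone, and camera was not run on that list.

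**Figure D4:**
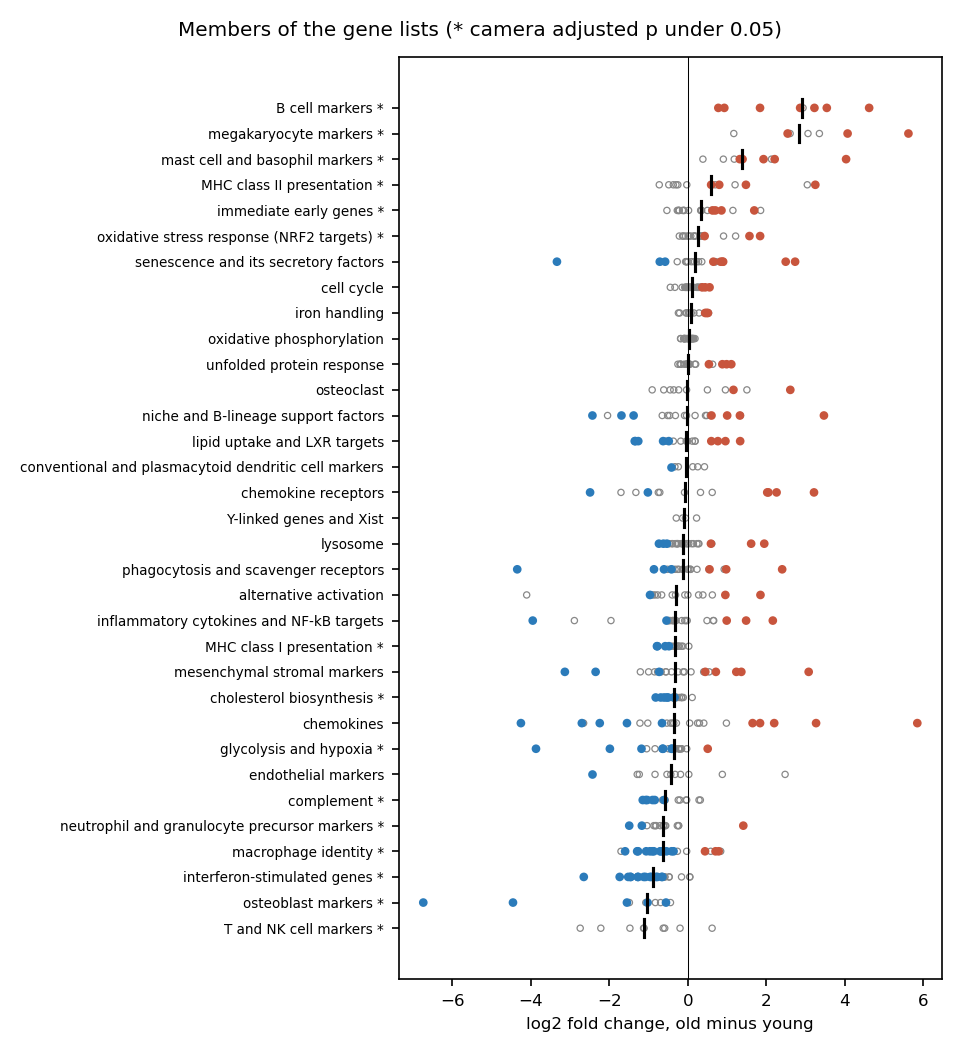
Log2 fold change, old minus young (x axis), of the tested members of 33 gene lists (y axis), with the list median as a black bar. Filled points passed an adjusted p of 0.05 (red higher, blue lower in old), open points did not, and a star marks the 15 lists with a camera adjusted p under 0.05; none of these 15 calls held with an estimated correlation.

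The median, the mean and the test had different signs for several lists. Chemokines had a median log2 fold change of -0.36 and mesenchymal stromal markers of -0.33, and both had an upward direction in camera. Chemokine receptors, osteoclast genes, the niche factors and the unfolded protein response genes also had a negative median with an upward direction. Lysosomal genes had a mean of 0.02 with a downward direction. Other groupings of the 6 libraries into 3 and 3 called up to 13 lists, against 15 for the ages.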

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

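Among these settings, the overlap and jump restrictions were chosen after the data were examined. With DESeq2 size factors, upper-quartile factors, scaling without the 50 most abundant genes, limma-voom, a non-robust dispersion, no filter, the stricter filter or the block, counts stayed within 1.5 times 909 higher and 731 lower. The DESeq2 test gave 1331 higher and 1137 lower genes, and testing for a fold of at least 2 left 137 and 91; the latter asks for a larger change, and the cause of the former was not tested. Leaving out 1 library gave between 418 and 1459 higher and between 294 and 1168 lower genes. Of 126 named genes called, 84 kept their call in every alternative they were tested in, 41 lost it without at least 1 library and 0 reversed. That count leaves out the fit without jumping genes and the test for a fold of at least 2, which 46 passed. Of the 133 named genes with a test, 130 were tested with the stricter filter and 99 among genes without an overlapping exon. With limma-voom, Igha and Gp1ba lost theirs (adjusted p = 0.0509 and 0.0568). With no filter, Igkv3-10, H2-Ob, H2-Ab1, Kif20a, Tcf4, Cldn5 and Itga2b did (0.0535, 0.0833, 0.0574, 0.0546, 0.0501, 0.0521 and 0.0638). Among genes named here outside the rule, Ccr7 and Cxcl9 lost theirs with limma-voom (0.0857 and 0.0815) and with the block. Hmga2 lost its call with no filter (0.0563) and with the block. The B cell markers Jchain and Cd79b and the complement gene Cfb lost theirs with the block (0.0928, 0.0868 and 0.0746). Other list members that are not named here also lost calls. Genes without an overlapping exon gave 659 and 512 of 9745 tested; without jumping genes there were 926 and 743.

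Same-numbered old and young libraries had deviations correlated at 0.192, 0.0295 and 0.204. For each old library this was its highest correlation with a young library, though old replicate 2 had 0.0257 with young replicate 3. Pairing by number therefore stays possible. The block was kept as an alternative because no label says that the numbers mark a shared batch. The replicate block gave 711 higher and 575 lower genes, and Cxcr5 lost its call (log2 fold change 2.21, adjusted p = 0.0979), as did Cxcr3, H2-Ob, H2-Ab1, H2-T23, B2m, Clec7a, Cdc20, Kif20a, Atf4, Ppp1r15a and Itga2b. Cxcr5 also lost it without each single library, at log2 fold changes from 1.87 to 2.59; fewer libraries were tested there.

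With an estimated correlation 0 of the 15 lists stayed called. The preset of 0.01 lies below most estimates, but complement, with an estimate of -0.016, lost its call too. With an estimate, camera tests on the 4 residual degrees of freedom, and with the preset on many more. For complement the loss therefore does not come from its correlation. For the other lists, correlation and the fewer degrees of freedom are not separated. MHC class II also lost its call with the stricter filter and with the block. T and NK cell markers lost theirs with the block. The fry test ended the calls of immediate early genes (adjusted p = 0.144), neutrophil markers (0.270), T and NK cell markers (0.270) and megakaryocyte markers (0.0695), and called lipid uptake (0.0352), cell cycle (0.0352) and osteoclast genes (0.0356). Osteoclast genes were also called with the stricter filter (0.0491) and endothelial markers without young replicate 1 (0.0490). Ddx3y was called without young replicate 3 (0.0285). Directions turned, in at least 1 fit, in 8 results that were not called. Over the fits that leave out 1 library the adjusted p ranged from 0.104 to 0.900 for chemokines, 0.294 to 0.701 for chemokine receptors, 0.513 to 0.984 for inflammatory genes, 0.525 to 1.000 for the lysosome, 0.437 to 1.000 for oxidative phosphorylation, 0.0598 to 0.766 for stromal markers and 0.297 to 0.958 for sex genes, and the log2 fold change of Eif2s3y from -0.32 to 0.030. Inflammatory genes also turned with the stricter filter (0.883) and stromal markers with the replicate block (0.929). The cause of these changes was not tested. Depth limits Cxcl13 and Cxcr5, with at most 52 counts in a library.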

Other observations

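Tests written after their result was seen are those of scaling, of reads shared between immunoglobulin genes, and of both explanations for jumping counts. Bootstrap intervals below resample genes as if independent and hold the libraries fixed, so they do not cover the spread between libraries. Beyond the comparisons above, some genes of fetal and juvenile growth were far lower in old libraries, chosen after their values were seen. Slc38a4, an imprinted amino acid transporter gene, went from 51.7 ± 10.4 to 2.84 ± 0.491 CPM (SD, n = 3), and Igf2bp3, an RNA-binding protein gene, from 18.3 ± 3.33 to 1.88 ± 0.111 CPM. Mest fell 7.97-fold and Igf2bp1 11.7-fold, while Cdkn1c and Hmga2 rose (Igf2bp3, Mest and Cdkn1c share 18.7%, 23.1% and 30.7% of their exon length with other gene models), and the Hmga2 call held only without young replicate 3 (adjusted p otherwise up to 0.134). As a hypothesis, a group of growth genes that decline after the juvenile period may be involved. The other 17 tested members had a median log2 fold change of -0.70, with a 95% bootstrap interval over genes from -1.20 to 0.02, and 2 were higher and 2 lower past the threshold, so the test did not decide.

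Macrophage identity genes were lower in old libraries. Whether scaling by a few very abundant genes plays a part was not decided for this list. TMM already trims genes of extreme abundance or change, so leaving out the most abundant genes could move little. Its median log2 fold change was -0.63 in the main fit, with a 95% bootstrap interval over genes from -0.91 to -0.27. With library sizes that leave out the 50 most abundant genes it was -0.63 as well. The median of all tested genes was -0.010 in the main fit and -0.012 in that setting. A lower share of leukocytes in the old cultures may contribute: leukocyte-restricted genes had a median of -0.45 (95% bootstrap interval -0.50 to -0.36), short of the -0.5 set in advance and below -0.3, so it cannot be told apart from lower expression per cell. Age itself stays open and untested.

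B-lineage genes and Cxcr5 were higher in old libraries. Reads shared between immunoglobulin genes are argued against as the whole account, since the 5 tested B cell markers that are not immunoglobulin genes had a median log2 fold change of 2.86. Residual B-lineage cells in the old cultures are a candidate source: 18 further B-lineage genes had a median of 2.11 (95% bootstrap interval 0.11 to 2.96), the same with Ighg1 at its bound, 10 higher and 2 lower, among them Pou2af1, while Blnk and Cd180, which macrophages also express, fell. Of the 18, 3 (Ighg1, Igha and Mzb1, with 57.2% of its exon length shared) had been seen to be high before; the other 15 had a median of 1.83 with an interval from -0.52 to 2.51 that covers 0, 7 higher and 2 lower, calls that held without each single library only for Pou2af1 and Tnfrsf13c. Attachment to the dish and removal of floating cells would deplete such cells, and an age difference in the animals stays open.

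Counts of 60 genes jumped between libraries of one age. C5ar1 had 7137 and 6716 counts in young and old replicate 2 and between 390 and 607 in the other 4, and Gm20431 had 5325 counts in old replicate 1 and 0 in old replicates 2 and 3, where the overlapping Ube2v1 (61.5% and 70.7% of the exon length of Ube2v1 and Gm20431) had 4193 and 3914 against 299. Of the 60, 100% had a jump beyond counting noise (exact binomial test, p under 1e-06). A gap as wide as the rule asks for exceeds counting noise at this depth. The rule therefore fixed this outcome, and no conclusion is drawn from it. The test covers the counting of reads and not the sampling of molecules before amplification. Overlapping gene models counted differently from library to library may account for part: 56.1% of those with a position overlap another gene, against 37.6% of other genes at that level (Fisher's exact test, one-sided p = 0.00355). Between ages 3 of the 60 were called: Igkc, Jchain and Gbp4 (adjusted p = 0.00873, 0.0179 and 0.0254). Igkc and Jchain are members of the B cell marker list above.

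Other splits of the 6 libraries into 3 and 3 were refitted, 10 in all with the real one, which is too few for a share under 0.05. Every split but the real one mixes the ages, so the age difference enters the spread within its groups. Its calls therefore do not show what libraries without a difference would give. The real split called 1640 genes and the highest other 1. It called 15 lists and the highest other 13; in each case 1 split, the real one, gave as many.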
